A study of Mus musculus with 8 samples.

How the data were processed

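Cultured lymph node stromal cells of BALB/c mice received siRNA against Eif4g3, or a control siRNA, at 400 pmol by lipofection and were collected after 48 h. The design text gives 7 plates per siRNA, and cells for the polysome samples were pooled, lysed and fractionated on a continuous sucrose gradient. RNA of the whole lysate (total RNA) and of the pooled heavy polysome fractions, which hold mRNAs loaded with many ribosomes, was labelled from 200 ng and hybridised to Agilent whole mouse genome 2-colour arrays. The series holds 8 arrays, 4 of total RNA and 4 of heavy polysome RNA. On every array Cy5 carried the Eif4g3 siRNA sample and Cy3 the control siRNA sample of the same fraction. There was no dye swap, so within a fraction a dye bias of a probe cannot be separated from a change of its transcript. Such a bias cancels in the difference between fractions where it is equal on all arrays. The labels do not say whether replicates came from separate cultures, so the p-values may reflect technical spread.

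The submitters' processing notes name Agilent Feature Extraction without a version. Per the file headers, the scanner tables hold spot and local background signals of both channels as intensity, and Feature Extraction 10.7.3.1 with protocol GE2_107_Sep09 made 7 of them. The header of total RNA array 2 gives version 10.5.1.1 and protocol GE2_105_Dec08. The deposited scanner tables also hold processed signals, background-subtracted and dye-normalised, and their ratio as log10 of Cy5 over Cy3. The deposited series matrix holds log2 of Cy5 over Cy3. Its values were checked against the processed signals and lay within 0.01 of their log2 ratio for at least 99.3% of 41267 probes on every array. Array medians of that table ran from -0.21 to 0.31, so it was not centred on 0. Probe coordinates are on mm8, as the headers state.

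Each array held 43379 non-control spots of 41174 probes. Gene names came from the scanner tables and were brought to current symbols through RefSeq gene records of GRCm38.p6, used for names only, which matched 23374 probes (56.8%). Up to 1989 spots carried another gene name than on total RNA array 1, and the names of that array were used throughout. Probes well above background, as marked by Feature Extraction, made up 57.5%, 49.3%, 51.8% and 51.1% in Cy3 on total RNA arrays 1 to 4 and 37.6%, 53.1%, 45.5% and 55.6% on heavy polysome arrays 1 to 4. In Cy5 these shares were 48.3%, 43.1%, 44.9% and 45.9% in total RNA and 49.7%, 51.9%, 47.3% and 53.5% in heavy polysome RNA. No spot was saturated, and 131 to 241 spots per array that were marked non-uniform or as population outliers were left out. The number of arrays limits the precision.

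Mean spot signals were corrected for median local background with normexp and an offset of 50, and log2 ratios were normalised within each array by loess with a span of 0.3. Control and marked spots had no weight in the curve. Spots of 1 probe were averaged, and the probe with the highest mean signal over the 8 arrays represented its gene. A gene was tested if its probe was well above background in at least 1 channel on at least 3 of the 4 arrays of at least 1 fraction, which left 14849 genes, 10827 of them with names from RefSeq. At least 3 values per fraction were required, and for the list tests the 8 missing values were filled with the mean of their fraction. Calculations used R 4.3.3, limma 3.58.1 and version 1.17.8 of data.table, and plots used Python 3.11.15 and matplotlib 3.10.9.

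Ratios were fitted in limma with 1 coefficient per fraction over all 8 arrays. Mean log2 ratios in total RNA and in heavy polysome RNA, and the difference heavy polysome minus total RNA, were tested against 0, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Counts were also made with a fold of at least 1.5. Fractionation in control cells was described by the Cy3 values after loess within and Aquantile normalisation between arrays, heavy polysome against total RNA. Equal RNA mass was labelled, so every value is relative to the other transcripts of its sample. On simulated data with 14849 genes, of which 100 were changed at each size, limma recovered 62% of 1.5-fold and 97% of 2-fold changes in total RNA, with 0 false calls. In heavy polysome RNA it recovered 62% and 95%, with 7 false calls. For the difference between fractions it recovered 8% of 1.5-fold and 63% of 2-fold changes, with 1 false call. The direction of a recovered change was checked in heavy polysome RNA only. Simulated noise was independent between genes, whereas real genes can vary together, so these rates may not hold for the real arrays.

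Before the data were examined, 26 gene lists were fixed, and the 24 with at least 5 tested members were tested with camera at a preset correlation of 0.01, adjusted over the 24 lists of a comparison. camera with an estimated correlation and fry were alternatives. The lists cover eIF4F and its regulators, other initiation factors, cytosolic and mitochondrial ribosomal proteins, elongation factors and other TOP mRNAs, oxidative phosphorylation, interferon-stimulated genes, NF-kB targets, antigen processing with MHC class I, MHC class II, lymph node stromal cell genes, extracellular matrix, peripheral tissue antigens, cell cycle, p53 targets, stress responses, cholesterol synthesis, hypoxia with glycolysis, eIF4E-sensitive mRNAs, histones, nuclear and non-coding RNAs, and markers of T cells, B cells, macrophages with dendritic cells, endothelial cells and epithelial cells. MHC class II, with 4 tested members, and B cells, with 1, were too small to test.

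The rule for named genes was also set in advance. It takes Eif4g3 with each of its probes. It takes the 10 largest increases and decreases per comparison among genes past the threshold with the same direction on all 4 arrays, leaving out clone, locus and predicted names. It adds up to 4 members of smallest adjusted p per list, the eIF4F members, Deaf1, Anpep and Aire, and the 5 largest changes each way in the control channel. The alternatives were other background corrections, normalisations, filters, probe summaries and thresholds, array weights, slide or replicate number as a block, a fit within 1 fraction, the series matrix values, and each array left out in turn. Alternatives chosen after seeing the data left out 3 arrays of low correlation, averaged heavy polysome arrays 2 and 4, used slide as a block for the control channel, and left out single arrays for the lists.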

Results

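Lymph node stromal cells, the fibroblast-like and vascular scaffold cells of lymph nodes, were studied after knockdown of Eif4g3, which encodes a scaffold protein of the translation initiation complex eIF4F. RNA of Eif4g3 siRNA cells was compared directly with RNA of control siRNA cells on 2-colour arrays, on 4 arrays of total RNA and 4 of heavy polysome RNA. Total RNA shows transcript abundance, and heavy polysome RNA comes from the gradient fractions that hold transcripts carrying many ribosomes. All values are log2 ratios of Eif4g3 siRNA over control siRNA unless stated, given as mean ± SD over the 4 arrays of a fraction, with adjusted p from limma. Across 14849 tested genes, the SD of the log2 ratios on an array ran from 0.27 to 0.45 in total RNA and from 0.30 to 0.51 in heavy polysome RNA. The mean correlation of an array with the others of its fraction, across genes, was lowest for heavy polysome array 1 (0.288), heavy polysome array 3 (0.317) and total RNA array 4 (0.326). Each of the 5 slides (3 for total RNA, 2 for heavy polysome RNA) held arrays of 1 fraction only, so no slide allows the fractions to be compared within it, and slide was fitted as a random block as an alternative.

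The siRNA target fell in both fractions on all 8 arrays. Eif4g3 transcript, read by probe A_52_P637573 (mm8 chromosome 4, 137478284 to 137478343), was 4.20-fold lower in total RNA (-2.07 ± 0.29, n = 4, adjusted p = 0.00202) and 5.49-fold lower in heavy polysome RNA (-2.46 ± 0.50, n = 4, adjusted p = 6.13e-04). A second probe, A_51_P438363 (137475547 to 137478087), gave -1.95 ± 0.75 and -2.07 ± 0.26. The change in heavy polysome RNA differed from that in total RNA by -0.39 (95% interval -0.95 to 0.18), which did not pass the threshold. Of the 21 measured members of the eIF4F list, Eif4g3 alone passed the threshold in total RNA. In heavy polysome RNA, Eif4e2, which encodes a cap-binding homologue of eIF4E, rose (1.09 ± 0.22, adjusted p = 0.00924; 0.61 ± 0.58 in total RNA, adjusted p = 0.0968), and Eif4a1, the RNA helicase subunit, fell slightly (-0.32 ± 0.05, adjusted p = 0.0413). The Eif4a1 call was lost with any 1 array left out except total RNA array 4 (adjusted p from 0.0556 to 0.151), and the Eif4e2 call without heavy polysome array 4 (0.0568). The paralogues Eif4g1 (-0.68 ± 0.87 in total and 0.00 ± 0.45 in heavy polysome RNA) and Eif4g2 (-0.48 ± 0.31 and 0.02 ± 0.68) did not pass, nor did Eif4e, Eif4a2, Eif4b or Pabpc1. Adjusted over the list alone, 1 member was lower in total RNA, and 1 was higher and 2 were lower in heavy polysome RNA. As a list, eIF4F genes did not shift in total RNA (median -0.14, camera adjusted p = 0.298) or in heavy polysome RNA (median 0.00, adjusted p = 0.685).

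In total RNA, which compares transcript abundance between Eif4g3 siRNA and control siRNA cells, 644 genes passed the threshold, 248 higher and 396 lower. With a fold of at least 1.5, 164 were higher and 253 lower. Fbn1, the gene of the microfibril protein fibrillin 1, rose 3.42-fold (1.77 ± 0.31, adjusted p = 0.00529), and Eps15, an adaptor of endocytosis, rose 3.25-fold (1.70 ± 0.27, adjusted p = 0.00362). Other genes among the largest increases were Gxylt2 (1.39 ± 0.53), the MAP kinase phosphatase gene Dusp2 (1.38 ± 0.56), the retinoic acid synthesis gene Aldh1a3 (1.30 ± 0.33), the connexin gene Gjb2 (1.28 ± 0.42), the cyclin G2 gene Ccng2 (1.28 ± 0.35), Cnrip1 (1.27 ± 0.25), Pqlc3 (1.22 ± 0.22) and the actin-regulating Arpc1b (1.22 ± 0.66). Bcap29, which encodes a protein of the endoplasmic reticulum membrane, fell 4.65-fold (-2.22 ± 0.47, adjusted p = 0.0125). Dnajc1, a co-chaperone gene of the same compartment, fell 3.01-fold (-1.59 ± 0.32, adjusted p = 0.00202). Abhd4 (2.82-fold), Gng12 (-1.42 ± 0.66), the osteopontin gene Spp1 (-1.35 ± 0.55), the kinase gene Mapkapk2 (-1.35 ± 0.27), the cholesterol ester hydrolase gene Nceh1 (-1.32 ± 0.35), Hmgn3 (-1.30 ± 0.34) and Tmem9b (-1.29 ± 0.58) also fell.

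Many of these total RNA calls were lost with 1 array left out. Such a fit has fewer arrays, so a lost call does not show that 1 array carried the change. The count was 178 without total RNA array 1, 129 without array 2, 52 without array 3 and 233 without array 4, and it was 1358, 307, 1118 and 253 without heavy polysome arrays 1 to 4, which share the estimate of the spread. Centring each array on the median of all its non-control spots, in place of loess, left the tested genes at a median of -0.77 with 0 calls. Spots too dim for testing enter that median, so a dye difference that varies with signal would stay in these ratios. Without total RNA array 2 (0.0567) or array 3 (0.0638) the Bcap29 call was lost. Of 51 named genes called in total RNA, 11 passed without each single array: Eif4g3, Fbn1, Eps15, Gxylt2, Aldh1a3, Ccng2, Cnrip1, Pqlc3, Dnajc1, Abhd4 and Neurl4. Gjb2 (0.0666) and Mapkapk2 (0.0553) were lost without total RNA array 3, and Dusp2, Nceh1 and Tmem9b without array 2 or 3 (0.0553 to 0.0875). Arpc1b was lost without array 2, 3 or 4 (0.0563 to 0.0897) and Hmgn3 without any total RNA array or heavy polysome array 4 (0.0526 to 0.119). Gng12 and Spp1 were lost without any total RNA array or heavy polysome array 2 or 4 (0.0553 to 0.143). All 51 kept their direction in every fit with an array left out.

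Interferon-stimulated genes were higher as a list in total RNA, with a median of 0.39 over 31 measured members, 26 of them above 0 (camera adjusted p = 2.14e-06). With an estimated correlation among members the adjusted p was 0.656, and fry gave 0.166. Ifih1, which encodes a sensor of double-stranded RNA, rose 2.14-fold (1.09 ± 0.11, adjusted p = 0.00936) and Oasl1 rose 1.84-fold (0.88 ± 0.08, adjusted p = 0.0127), while Ifit1 (0.51 ± 0.20, adjusted p = 0.0555) did not pass. These 2 members passed over all genes, and 6 passed higher when adjusted over the list alone. The call for Ifih1 was lost without total RNA array 3 (adjusted p = 0.0562), and that for Oasl1 without total RNA array 2 (0.0632) or array 3 (0.0731). The median of the list was 0.42, 0.55, -0.01 and 0.39 on total RNA arrays 1 to 4. Under median centring it was -0.34 against -0.77 for all genes.

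Extracellular matrix genes were lower as a list in total RNA, with a median of -0.27 over 46 members (camera adjusted p = 0.0341; adjusted p = 0.656 with an estimated correlation). Col18a1 (-0.59 ± 0.12), the collagen I gene Col1a2 (-0.46 ± 0.28) and Sparc (-0.55 ± 0.19) fell, whereas Fbn1 rose. Adjusted over the list alone, 1 passed higher and 6 lower. The calls for Col18a1, Col1a2 and Sparc were lost without any 1 total RNA array or heavy polysome array 2 or 4 (0.0575 to 0.152). The list call was lost without total RNA array 1 (adjusted p = 0.0886), total RNA array 2 (0.163) or heavy polysome array 3 (0.0539), and with the mean of all tested probes of a gene (0.0701). Under median centring it was kept (median -1.19 against -0.77 for all genes, adjusted p = 0.0173), though with an estimated correlation 0 lists passed there (lowest adjusted p = 0.307). Replication-dependent histones (median 0.17, 32 members, camera adjusted p = 0.00502) and cytosolic ribosomal protein genes (median 0.14, 83 members, 1.63e-04) were also higher as lists, by small amounts. With an estimated correlation their adjusted p was 0.656 and 0.727, and the only member of either list to pass was Rpl41 (0.47 ± 0.23), with 0 members adjusted over the list alone. Rpl41 was lost without total RNA array 2, 3 or 4 or heavy polysome array 2 or 4 (0.0613 to 0.119). The histone call was lost without total RNA array 2 (adjusted p = 0.163). Under median centring both calls were lost: histones had a median of -0.66 against -0.77 for all genes (adjusted p = 0.314), and ribosomal protein genes had -0.74 with camera's direction down (0.210). Cell cycle genes were higher as a list with a smaller median (0.06, 41 members, camera adjusted p = 0.0341, or 0.656 with an estimated correlation). Birc5 (0.59 ± 0.15) and Cdca3 (0.75 ± 0.14) were higher, with 5 higher and 1 lower adjusted over the list alone. Under median centring the median of cell cycle genes was -0.84 against -0.77 for all genes, with camera's direction down (0.538). The cell cycle call was lost without total RNA array 1 (adjusted p = 0.0638) or array 4 (0.0673), and without the 3 arrays of lowest correlation (0.0555). Birc5 was lost without total RNA array 1, 2 or 3 (0.0785 to 0.0864) and Cdca3 without array 2, 3 or 4 (0.0572 to 0.0731).

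Heavy polysome RNA shows which transcripts were more or less abundant in the heavy polysome fractions after knockdown. Here 1310 genes passed, 717 higher and 593 lower, of which 396 and 292 had a fold of at least 1.5. Fbn1 (3.19-fold, 1.68 ± 0.54, adjusted p = 0.00289) and Eps15 (3.02-fold, 1.59 ± 0.47) rose again. The interferon-inducible Ifi27l2a (1.54 ± 0.34), Gjb2 (1.52 ± 0.52), the 14-3-3 gene Ywhah (1.52 ± 0.46), Ss18 (2.82-fold), Pqlc3 (2.84-fold), the ESCRT gene Chmp3 (1.47 ± 0.39), Ccng2 (1.45 ± 0.19) and Cnrip1 (1.37 ± 0.13) were also higher. Bcap29 (3.50-fold, -1.81 ± 1.09, adjusted p = 0.0133), Dnajc1 (2.98-fold, -1.58 ± 0.20, adjusted p = 7.53e-04) and the stromelysin gene Mmp3 (2.92-fold, -1.55 ± 0.81, adjusted p = 0.00871) fell. Spp1 (-1.48 ± 0.83), Gna14 (-1.41 ± 0.51, with Cy5 signal well above background on 3 of 4 arrays), the myeloid receptor gene Trem2 (-1.39 ± 0.71), Neurl4 (-1.37 ± 0.20) and Nceh1 (-1.34 ± 0.58) were lower as well. Spp1 and Trem2 were lowest on heavy polysome array 3 (-2.66 and -2.34). There the median of 8 macrophage genes was -0.61, against 0.03, -0.02 and -0.10 on arrays 1, 2 and 4. That list did not pass (camera adjusted p = 0.378), and a changed share of other cells was not tested. Anpep, which encodes aminopeptidase N and has been studied in these cells before, fell in heavy polysome RNA (-0.98 ± 0.20, adjusted p = 0.00641) and in total RNA (-0.75 ± 0.42, adjusted p = 0.0280), though its total RNA call was lost without any 1 of the 4 total RNA arrays (adjusted p from 0.0547 to 0.0864) or without heavy polysome array 4 (0.0572). Deaf1, a transcriptional regulator of peripheral tissue antigens, was at 0.02 ± 0.50 and 0.26 ± 0.28 in total and heavy polysome RNA and passed in neither, and Aire did not reach the signal needed for testing.

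Without heavy polysome array 2 the count was 583, and without heavy polysome array 4 it was 353. These arrays correlated at 0.884 across genes, more than any other pair, and 451 genes passed when their mean was used as 1 replicate, a check chosen after seeing the data. A fit on the heavy polysome arrays alone gave 390 genes, and median centring gave 0. Of 70 named genes called, 29 passed without each single array: Eif4g3, Fbn1, Eps15, Ifi27l2a, Gjb2, Ywhah, Ss18, Pqlc3, Chmp3, Ccng2, Cnrip1, Gxylt2, Aldh1a3, Dnajc1, Mmp3, Gna14, Neurl4, Nceh1, Abhd4, Anpep, Col18a1, Col5a3, H1f2, Hk1, Ly6a, Birc5, Cdca3, Bcl2l1 and Ndufb9. Bcap29 was lost without heavy polysome array 2 (adjusted p = 0.0537) or array 4 (0.0686), and Spp1 (0.0631) and Trem2 (0.0565) without array 4.

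Extracellular matrix genes were lower as a list in heavy polysome RNA too (median -0.20, camera adjusted p = 0.0288; adjusted p = 0.845 with an estimated correlation). Among 46 members, 8 fell, including Col18a1 (-0.95 ± 0.36), Col5a3 (-0.77 ± 0.14), Col5a1 (-0.49 ± 0.14) and Mmp3, a protease of the matrix, and 1 rose, Fbn1. Adjusted over the list alone, 10 were lower and 4 higher. Col5a1 was lost without heavy polysome array 1 (0.0764), 2 (0.0972) or 4 (0.113). Histones were higher as a list (median 0.18, camera adjusted p = 0.0288; 0.941 with an estimated correlation), with 1 of 32 members past the threshold over all genes and over the list alone, the linker histone gene H1f2 (0.63 ± 0.18, adjusted p = 0.00549). Both list calls were lost without heavy polysome array 2 (adjusted p = 0.232) or array 4 (0.176). Under median centring the matrix call was lost (0.130) and the histone call was kept (3.27e-05). Of the interferon-stimulated genes, 5 of 31 rose, among them Ifih1 (0.77 ± 0.46), Oasl1 (0.56 ± 0.41), Ifit1 (0.54 ± 0.32) and Eif2ak2 (0.54 ± 0.18), the gene of a kinase activated by double-stranded RNA. Adjusted over the list alone, 6 were higher and 1 lower, and the list did not pass (median 0.26, camera adjusted p = 0.0726; 0.941 with an estimated correlation; fry 0.407), though by camera at the preset correlation it did without heavy polysome array 1 (1.36e-04), heavy polysome array 3 (0.0432) or total RNA array 3 (0.0413), without the 3 arrays of lowest correlation (5.82e-07), under median centring (3.27e-05) and with the mean of all tested probes (0.0155). With an estimated correlation 0 of the 24 lists passed in heavy polysome RNA in any of these settings (lowest adjusted p = 0.346). The calls for Ifih1 were lost without heavy polysome array 2 (0.0672) or array 4 (0.0601), and those for Oasl1 without heavy polysome array 2, 3 or 4 or total RNA array 2 or 3 (0.0619 to 0.158). Ifit1 was lost without total RNA array 2 (0.0540) or heavy polysome array 2 (0.119), 3 (0.0525) or 4 (0.115), and Eif2ak2 without heavy polysome array 2 (0.0566), 3 (0.0643) or 4 (0.0747). Stromal cell genes went both ways: of 21 members, Ly6a (1.11 ± 0.57) and the chemokine gene Cxcl12 (0.78 ± 0.47) rose, and 4 fell, among them Anpep, Pdgfra (-0.65 ± 0.13) and Enpp2 (-1.07 ± 0.64), with 2 higher and 6 lower adjusted over the list alone. Cxcl12 was lost without heavy polysome array 2 (0.0695) or 4 (0.0863), Enpp2 without heavy polysome array 2 (0.0529), 3 (0.0542) or 4 (0.0863), and Pdgfra without heavy polysome array 4 (0.0601). In total RNA, Anpep alone of these passed, with 1 higher and 4 lower adjusted over the list alone. Under 12 of 24 alternatives Enpp2 also passed there, and Ly6a did under 11, Cxcl12 under 3 and Pdgfra under 1. Among hypoxia and glycolysis genes, Hk1 (-1.05 ± 0.17) and Gpi1 (-0.47 ± 0.16) fell and 0 of 28 rose, with 5 lower adjusted over the list alone. Gpi1 was lost with any 1 array left out except total RNA arrays 1 and 4 (0.0637 to 0.126). Rpl41 (0.57 ± 0.02) and Rps27l (0.38 ± 0.15) rose among 83 ribosomal protein genes, and Birc5 (0.75 ± 0.23) and Cdca3 (0.81 ± 0.34) among 41 cell cycle genes, with 1 and 2 higher adjusted over the list alone. Rpl41 was lost without heavy polysome array 4 (0.0530), and Rps27l without total RNA array 2 (0.0501) or heavy polysome array 2, 3 or 4 (0.0565 to 0.123). The ribosomal protein list did not pass in heavy polysome RNA (median 0.00, camera adjusted p = 0.940), though it was higher without heavy polysome array 1 (6.54e-05).

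**Figure D1:**
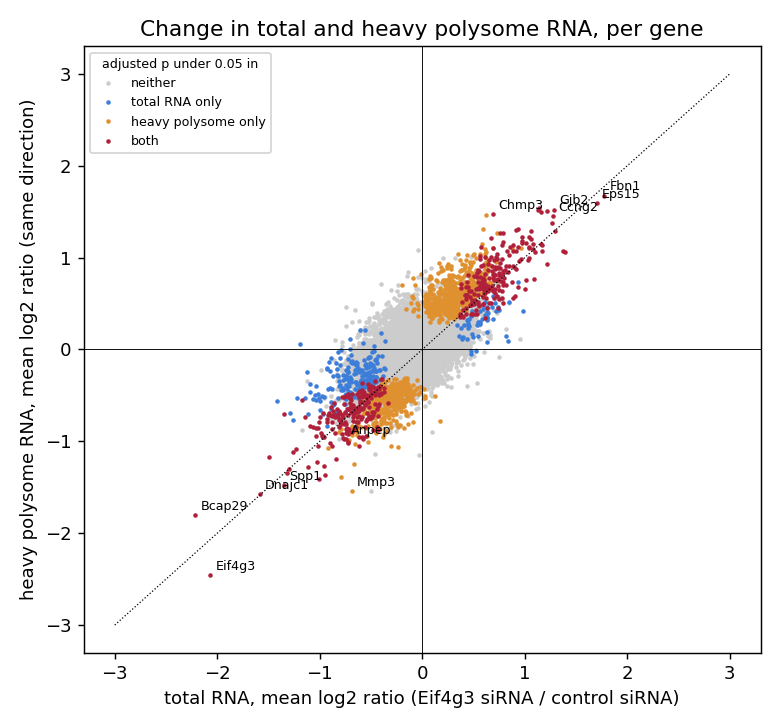
Mean log2 ratio of Eif4g3 siRNA over control siRNA in total RNA (horizontal) and heavy polysome RNA (vertical) for 14849 genes, coloured by the fraction in which adjusted p was below 0.05, with equal change on the dotted diagonal. The 401 genes called in both fractions lie along the diagonal, with Eif4g3 and Bcap29 at the lower left and Fbn1 and Eps15 at the upper right.

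The same genes moved in both fractions more often than independent calls would give. Among genes called in total RNA and in heavy polysome RNA, 401 were shared. All 401 had the same direction, 196 higher and 205 lower, where independent calls would give about 12 and 16. The fractions share the estimate of each gene's spread, so their calls are not independent, and 12 and 16 are too low a reference. Heavy polysome RNA is also a part of the RNA of cells given the same siRNAs. A change of abundance would therefore appear in both fractions, and shared direction alone says nothing about loading. Ratios of the 2 fractions correlated at r = 0.695 across genes, which are not independent replicates. Of the 644 genes called in total RNA, 632 had the same sign in heavy polysome RNA, and of the 1310 called in heavy polysome RNA, 1291 had the same sign in total RNA. Passing in 1 fraction alone, as 243 and 909 genes did, does not show a difference between fractions. Both fractions had the same dye orientation.

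**Figure D2:**
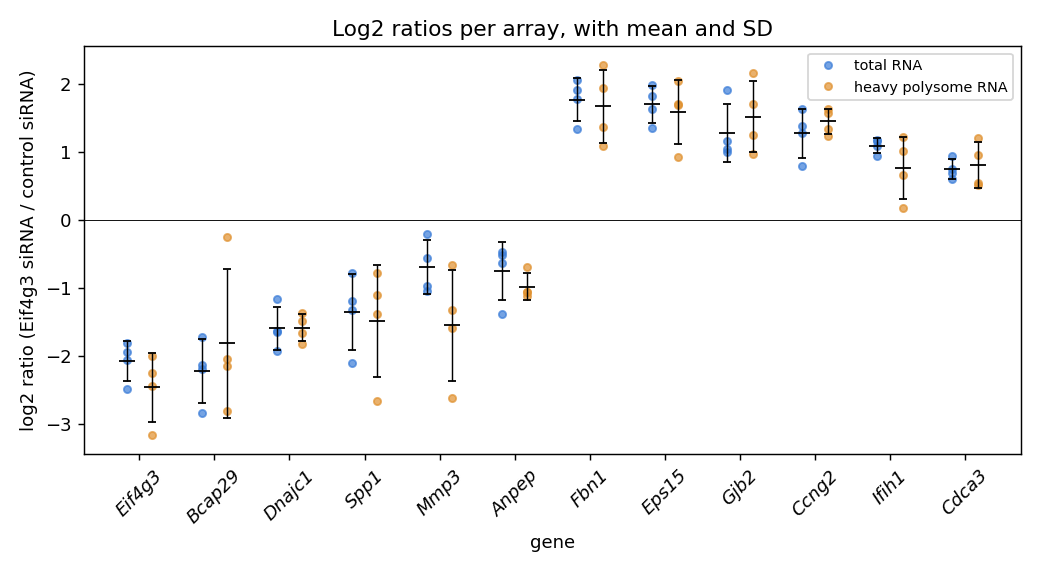
Log2 ratio of Eif4g3 siRNA over control siRNA of 12 genes on each of the 4 total RNA and 4 heavy polysome arrays, with points for arrays and bars for mean ± SD. Eif4g3 lies below 0 on all 8 arrays, and Fbn1 and Eps15 lie above 0 on all 8.

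The difference between fractions asks whether the polysome loading of single transcripts changed beyond their abundance, relative to other transcripts. Equal RNA mass was labelled and each array was normalised on its own spots. A general change in loading, shared by most transcripts, would therefore not be seen here. By limma, 0 genes passed (smallest adjusted p = 0.846). An unadjusted p below 0.05 was found for 784 of 14849 genes, a share close to the 0.05 that chance alone gives. Mmp3 was at -0.69 ± 0.39 in total and -1.55 ± 0.81 in heavy polysome RNA, a difference of -0.86 (95% interval -1.68 to -0.03). Chmp3 differed by 0.78 (0.27 to 1.29), Col5a3 by -0.49 (-0.78 to -0.19) and Hk1 by -0.44 (-0.72 to -0.15), and none of these passed after adjustment. For Fbn1 the difference was -0.10 (-0.69 to 0.50), and for Dnajc1 it was 0.01 (-0.39 to 0.41). The 4 heavy polysome values all lay above or all below the 4 total RNA values in 537 genes (3.62%), where chance gives 2.86%. The median gene had a 95% interval of 0.40 to either side on the log2 scale (a factor of 1.32). In simulated data, with noise independent between genes, limma recovered 8% of 1.5-fold and 63% of 2-fold differences between fractions.

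As lists, cytosolic ribosomal protein genes were lower in heavy polysome than in total RNA (median difference -0.13 against 0.06 for all genes, camera adjusted p = 7.45e-05), with 0 of 83 members past the threshold over all genes or over the list alone. With an estimated correlation the adjusted p was 0.832. Heavy polysome array 1 set this apart: the list's median there was -0.57, against 0.31, 0.06 and 0.25 on heavy polysome arrays 2 to 4 and 0.12 to 0.28 on the total RNA arrays, and without array 1 the adjusted p was 0.878. Under median centring the list's difference was 0.78, equal to the shift of all genes, and camera's direction was up (adjusted p = 0.0501). Interferon-stimulated genes also had a lower median difference (-0.08, adjusted p = 0.0214; 0.832 with an estimated correlation), also lost without heavy polysome array 1 (adjusted p = 0.778), heavy polysome array 3 (0.129) or total RNA array 1 (0.0618), 2 (0.227) or 4 (0.149). Under median centring it was 0.67 against 0.78 for all genes (adjusted p = 0.715). Their median was -0.15 on that array and 0.71, 0.14 and 0.44 on the others. The 22 other lists did not pass for the difference after loess with all 8 arrays and 1 probe per gene. By camera at the preset correlation, histones were higher without heavy polysome array 1 (adjusted p = 0.00481) and NF-kB targets lower without total RNA array 2 (0.0441) or with the mean of all tested probes (0.0400). Without the 3 arrays of lowest correlation, histones were higher (3.17e-06) and matrix genes lower (0.00441). Under median centring, camera's direction was up for oxidative phosphorylation (median 0.95 against 0.78 for all genes, 6.99e-04), mitochondrial ribosomal proteins (0.93, 0.0470) and nuclear and non-coding RNAs (0.77, 0.0470), and down for epithelial genes (0.02, 0.0470). With an estimated correlation 0 of the 24 lists passed in any of these settings (lowest adjusted p = 0.738).

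In control siRNA cells, the Cy3 channel describes the fractionation itself. Relative to total RNA, 316 genes were lower and 2 were higher in heavy polysome RNA. The lowest named genes were Gas5, a spliced non-coding host of small nucleolar RNAs, at 6.50-fold lower (-2.70, SE 0.18, adjusted p = 4.94e-04), Pkig, an inhibitor gene of protein kinase A, at 6.01-fold lower (-2.59, SE 0.17), Selenow (-2.45, SE 0.47), Tmem134 (-2.28, SE 0.24) and Metrn (-2.24, SE 0.28). In the Eif4g3 siRNA channel the same contrast gave -2.84 for Gas5 and -2.50 for Pkig. Gas5 was still well above background in Cy3 on all 4 heavy polysome arrays, so these fractions also held non-coding RNA. Higher in heavy polysome RNA were Sipa1l2 (0.89, SE 0.17, adjusted p = 0.0292) and Tulp4 (0.67, SE 0.13, adjusted p = 0.0340). All 7 measured nuclear and non-coding RNAs had values below 0, with a median of -1.54 (camera adjusted p = 1.76e-06; adjusted p = 0.196 with an estimated correlation; fry 0.00242). Of these, Gas5 and the nuclear RNA Malat1 (-1.94, SE 0.24, adjusted p = 0.00533) passed over all genes, and 6 passed when adjusted over the list alone. Hypoxia and glycolysis genes (median 0.25, 28 members, camera adjusted p = 0.00924) and antigen processing genes (median 0.22, 22 members, 0.0435) were higher as lists, both at adjusted p = 0.970 with an estimated correlation and with 0 members higher over all genes or over the list alone. The antigen processing gene H2-T22 went the other way (-1.85, SE 0.36, adjusted p = 0.0302) and was the only member of either list to pass. Ribosomal protein genes Rps29 (-1.29, SE 0.17) and Rpl41 (-1.14, SE 0.19) were lower, and the list did not pass (adjusted p = 0.215).

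This contrast compares channels across arrays, so array effects do not cancel. The count was 194 and 206 without total RNA arrays 3 and 4, 86, 118 and 138 without heavy polysome arrays 2, 3 and 4, and 0 without the 3 arrays of lowest correlation. It was 92 with median-centred processed signals and 27 in the Cy5 channel.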

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

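Chosen only after the results were seen were the tests that leave a single array out of a list and the permutation of the ribosomal list's medians. Among 184 groups of 4 arrays looked at, 14 had 1 array far from the other 3 (by Dixon's test of the gap over the range), and chance gives about 5%. In total RNA, array 1 stood apart for Hmgn3 (-0.80, others -1.53 to -1.43), Cnrip1 (1.64, others 1.12 to 1.18), Pabpc1 (-0.53, others -0.13 to -0.09) and Cxcl12 (0.81, others 0.35 to 0.38). Total RNA array 4 stood apart for the cyclin gene Ccnd3 (-1.94, others -1.07 to -1.02), Shmt2 (-1.19, others -0.55 to -0.43) and Eif4e2 (-0.25, others 0.83 to 1.02), and array 3 for Vldlr (-0.91, others -0.32 to -0.26). In heavy polysome RNA, array 3 stood apart for Gxylt2 (0.88, others 1.11 to 1.15), Sparc (0.24, others -0.50 to -0.39), Eif4b (0.22, others -0.04 to -0.01) and H2-M3 (-1.28, others -0.49 to -0.43). Heavy polysome array 2 stood apart for Anpep (-0.68, others -1.11 to -1.05), and array 1 for Rps27l (0.15, others 0.44 to 0.48).

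Cytosolic ribosomal protein genes differed between fractions as a list, with a median difference of -0.13 (heavy polysome minus total RNA; camera adjusted p = 7.45e-05 at the preset correlation, 0.832 with an estimated correlation, and 0.973 by fry). Against a general lower loading of these mRNAs after knockdown, the call was lost without heavy polysome array 1 (camera adjusted p = 0.878) and stayed at 0.00746 or below without any other single array. The list's median over the 4 arrays was 0.18 ± 0.07 in total and 0.01 ± 0.40 in heavy polysome RNA, with a two-sided exact permutation p of 0.629, where 4 against 4 arrays can reach 0.0286. A candidate explanation is therefore heavy polysome array 1 alone, whose Cy3 channel had the lowest share of probes well above background (37.6%). Why that array differs was not tested.

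Interferon-stimulated genes also differed between fractions as a list, with a median difference of -0.078 (camera adjusted p = 0.0214 at the preset correlation, 0.832 with an estimated correlation, and 0.973 by fry). The call was lost without heavy polysome array 1 (0.778), heavy polysome array 3 (0.129) or total RNA array 1 (0.0618), 2 (0.227) or 4 (0.149).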

How the results depend on the processing

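The alternatives that left out 3 arrays of low correlation, averaged heavy polysome arrays 2 and 4, used slide as a block for the control channel, or left out single arrays for the lists were chosen after the results were seen. Where no cause is named, the cause was not tested. Signal over background limits dim genes: 37.6% to 57.5% of probes were well above background in Cy3.

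The count of 644 genes in total RNA became 1479 with Feature Extraction's processed signals (806 higher and 673 lower, 54.5% higher against 38.5%), 1479 with series matrix values, 1402 with ratios scaled between arrays, 2656 with array weights, 1503 with slide as a random block (correlation -0.267) and 3225 without the 3 arrays. It became 56 at adjusted p under 0.01, 21 with treat against a fold of 1.2 and 305 with heavy polysome arrays 2 and 4 averaged. For heavy polysome RNA, 1310 became 2080, 2079, 7478, 2642 and 2439 with processed signals, series matrix values, array weights, slide block and without the 3 arrays. It became 335, 142, 390 and 451 at adjusted p under 0.01, with treat, with that fraction's arrays alone and with arrays 2 and 4 averaged. Stricter thresholds call fewer genes by construction. A negative slide correlation narrows the standard error of a fraction's mean, so the higher counts with slide as a block do not show stronger changes. Array weights put 3.14 and 6.12 on heavy polysome arrays 2 and 4. Median centring in place of loess gave 0 genes in total RNA and 0 in heavy polysome RNA, with the median of all genes at -0.77 in total RNA. This centring does not remove a dye difference that varies with signal. The processed signals, which gave more calls than loess, were themselves dye-normalised, so they are not an independent check of the loess step. Leaving out 1 array gave 52 to 1358 genes in total RNA and 353 to 1560 in heavy polysome RNA. For the difference, limma gave 0 genes under each alternative but array weights, which gave 5. Deviations of same-numbered arrays of both fractions correlated across genes at -0.02, 0.17, -0.11 and -0.30. Between differently numbered arrays they ran from -0.51 (total RNA array 4 with heavy polysome array 2) to 0.47 (total RNA array 1 with heavy polysome array 2). These values cannot show whether the replicate numbers pair the arrays, and the labels do not say. The control channel's 318 became 92 with median-centred processed Cy3 signal, 27 in Cy5, 61 with a replicate block, 0 without the 3 arrays and 86 to 346 with 1 array left out. Its genes' own values were not rerun.

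The numbers of lists past the threshold (5 in total RNA, 2 in heavy polysome RNA, 2 for the difference, 3 in the control channel) were 0, 0, 0 and 0 with an estimated correlation and 0, 0, 0 and 1 with fry. Median centring gave 6 in total RNA, 4 in heavy polysome RNA and 4 for the difference, and leaving out the 3 arrays gave 7, 7 and 2. Without those 3 arrays fry gave 5, 3 and 0 lists, and with the mean of all tested probes it gave 1, 0 and 0. Leaving out 1 array gave 3 to 7 in total RNA, 0 to 7 in heavy polysome RNA and 1 to 2 for the difference. With 1 array left out, an estimated correlation gave 0 lists throughout, and fry gave 11 in total RNA and 4 in heavy polysome RNA without heavy polysome array 1 and 0 otherwise.

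Among values of named genes past the threshold, 883 of 1223 in total RNA and 1220 of 1678 in heavy polysome RNA kept direction and threshold over the alternatives. A further 332 and 458 kept only their direction, and none passed under median centring. Median centring reversed Chmp3 (-0.17), Birc5 (-0.31), Cdca3 (-0.20), Bcl2l1 (-0.51), Fgf2 (-0.051), Rpl41 (-0.35) and Mrps24 (-0.47) in total RNA, each above the -0.77 of all genes, and the mean of all tested probes reversed Bcl2l1 (-0.015). Eif4g3 ranged from -3.02 to -1.93 in total RNA and from -2.61 to -2.12 in heavy polysome RNA.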

Other observations

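Chosen only after the results were seen were the tests of other probes, of the correlation between fractions, of lists matched on signal, of single arrays left out of lists, of gene types and of splits and signs of the arrays. Several gene groups not described so far held single called members and did not pass as lists with all 8 arrays, with camera adjusted p of 0.0910 or more in total RNA and 0.134 or more in heavy polysome RNA. Of mRNAs known as sensitive to eIF4E (19 measured), the growth and survival genes Fgf2 (0.71 in total RNA, 0.81 in heavy polysome RNA), Bcl2l1 (0.38 and 0.71) and Birc5 (0.59 and 0.75) rose in both fractions, while Ccnd1 (-0.55) and Ccnd3 (-1.27) fell in total RNA and Mmp3 fell in heavy polysome RNA. Adjusted over the list alone, 3 were higher and 4 lower in total RNA, and 3 higher and 2 lower in heavy polysome RNA. The total RNA calls were lost without any 1 total RNA array for Fgf2 and Ccnd3 (0.0581 to 0.0881), also without heavy polysome array 2 or 4 for Bcl2l1 and Ccnd1 (0.0758 to 0.168), and without total RNA array 1, 2 or 3 for Birc5 (0.0785 to 0.0864). Fgf2 was lost in heavy polysome RNA without array 4 (0.0530). Median centring reversed Fgf2, Bcl2l1 and Birc5 in total RNA, and the mean of all tested probes also reversed Bcl2l1 there. Of 23 p53 targets, Btg2 (-0.87 and -0.71) and Phlda3 (-0.68 and -0.60) fell in both fractions, and Pmaip1 (0.80) and Trp53inp1 (0.42), which promote cell death, rose in heavy polysome RNA, with 3 lower in total RNA and 2 higher and 4 lower in heavy polysome RNA adjusted over the list alone. Trp53inp1 was lost with any 1 array left out except total RNA array 1 (0.0519 to 0.110), and Pmaip1 without heavy polysome array 2 (0.0616) or 4 (0.0509). Btg2 was lost in each fraction with 5 of the 8 arrays left out in turn (0.0519 to 0.107 in total RNA, 0.0591 to 0.123 in heavy polysome RNA), and Phlda3 in total RNA without array 3 (0.0684) and in heavy polysome RNA without array 4 (0.0552). Of 28 hypoxia and glycolysis genes, Hk1 (-0.62) and Eno1 (-0.92) fell in total RNA, with 4 lower adjusted over the list alone. Hk1 was lost there without array 2 (0.0541) or 3 (0.0652), and Eno1 without array 1, 2 or 3 (0.0615 to 0.0820). Of 30 stress response genes, the amino acid synthesis genes Aldh18a1 (-0.53) and Shmt2 (-0.65) fell in total RNA, and in heavy polysome RNA Atf3 (0.57) and Sel1l (0.55) rose and Vldlr (-0.52) fell, with 5 lower in total RNA and 2 higher and 1 lower in heavy polysome RNA adjusted over the list alone. Aldh18a1 and Shmt2 were lost without any 1 total RNA array or heavy polysome array 2 or 4 (0.0508 to 0.142). Atf3 was lost without total RNA array 2 or any 1 heavy polysome array (0.0541 to 0.0844), Sel1l without any 1 array except total RNA arrays 1 and 4 (0.0604 to 0.102), and Vldlr without total RNA array 1 or 2 or heavy polysome array 2, 3 or 4 (0.0510 to 0.167).

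The 24 measured cholesterol synthesis genes did not shift as a list in total RNA (median -0.13, camera adjusted p = 0.0910) or in heavy polysome RNA (median -0.08, 0.499). Of 22 NF-kB targets, Bcl3 fell in both fractions (-0.68 and -0.90) and Tnfaip3 (0.41) rose in heavy polysome RNA. Of 22 antigen processing and MHC class I genes, the chaperone gene Canx (-0.97) fell in total RNA and H2-M3 (-0.67) in heavy polysome RNA. Of 81 oxidative phosphorylation genes, Ndufb9 fell in both fractions (-0.66 and -0.70) and Uqcrh (0.47) rose in heavy polysome RNA. Of 77 mitochondrial ribosomal protein genes, Mrps24 rose in both (0.47 and 0.49), and Mrps31 (-0.48) and Mrpl58 (-0.57) fell in heavy polysome RNA. Of 27 other initiation factors, Eif3j1 (0.44) and Eif1ax (0.40) rose in heavy polysome RNA, and 0 of 12 TOP mRNAs passed in either fraction. Of 16 measured peripheral tissue antigens, the heart troponin gene Tnnt2 (0.80) rose in heavy polysome RNA, and 0 passed in total RNA. Among markers of other cell types, Csf1r of 8 macrophage genes (-0.57) and Krt19 of 5 epithelial genes (-0.80) fell in total RNA. In heavy polysome RNA Krt19 (-0.69) fell and Lck (0.34) of 6 T cell genes rose, and 0 of 6 endothelial genes passed in either fraction. Of the 7 nuclear and non-coding RNAs, 0 passed in either fraction. Adjusted over the list alone, counts were 1 higher in total and 3 higher in heavy polysome RNA for nuclear and non-coding RNAs, and 1 higher in total RNA for TOP mRNAs. For endothelial genes 1 was higher and 1 lower in total RNA and 1 lower in heavy polysome RNA, and for peripheral tissue antigens 1 was higher and 1 lower in heavy polysome RNA. For mitochondrial ribosomal proteins 0 passed in either fraction, for Uqcrh and H2-M3 the call was lost, and for the other lists of this paragraph the named members passed again. Most of these calls were also lost with 1 array left out, which by itself does not show that 1 array carried them. In total RNA, Bcl3, Canx, Mrps24 and Csf1r were lost without any 1 total RNA array or heavy polysome array 2 or 4 (0.0613 to 0.168), Ndufb9 without any 1 total RNA array (0.0541 to 0.0927) and Krt19 without total RNA array 1, 2 or 3 (0.0684 to 0.0937). Of the heavy polysome calls, Mrpl58 was lost without each of the 8 arrays (0.0508 to 0.107), and Mrps31, Eif1ax and Tnfaip3 without any 1 array except total RNA array 4 (0.0525 to 0.110). H2-M3 and Uqcrh were lost without any 1 array except total RNA arrays 1 and 4 (0.0595 to 0.128). Eif3j1 was lost without total RNA array 2 or 3 or heavy polysome array 1, 3 or 4 (0.0518 to 0.0750), and Lck without total RNA array 2 or 3 or heavy polysome array 2, 3 or 4 (0.0653 to 0.151). Mrps24, Tnnt2 and Krt19 were lost without heavy polysome array 2 or 4 (0.0754 to 0.103) and Bcl3 without array 4 (0.0517), while Ndufb9 passed without each array.

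Some of these lists passed with 1 array left out or under median centring by camera at the preset correlation, and 0 of the 24 lists did so with an estimated correlation in any of these settings (lowest adjusted p = 0.307 in total RNA and 0.346 in heavy polysome RNA). In total RNA without array 4, stress response (0.0148) and hypoxia and glycolysis genes (0.0466) were lower and oxidative phosphorylation genes higher (0.0466). In heavy polysome RNA without array 1, hypoxia and glycolysis genes were lower (0.0121) and oxidative phosphorylation genes (0.00261) and nuclear and non-coding RNAs (0.0216) higher. Under median centring, where the median of all genes in total RNA was -0.77, mitochondrial ribosomal protein (-0.96, adjusted p = 0.0173) and oxidative phosphorylation genes (-0.86, 0.0205) lay below that median in total RNA, and T cell (-0.09, 0.0139) and epithelial genes (0.01, 0.00699) above it. With an estimated correlation these were at 0.896, 0.896, 0.307 and 0.307. The same centring made NF-kB targets lower in heavy polysome RNA (-0.07, 0.0233) and nuclear and non-coding RNAs higher (0.16, 0.00181), both at 0.961 with an estimated correlation.

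The shared direction of 401 genes in total and heavy polysome RNA was weighed against effects of the array. Against hybridisation or dye effects of single probes, 200 of 224 other probes of 161 of these genes (89.3%, exact 95% interval 84.5% to 93.0%) had the sign of the reported probe, while the share over 6542 other probes of all genes was 66.4%. The other probes had smaller changes, with medians of 0.26 and -0.27 where the reported probes had 0.74 and -0.68. A dye effect common to all probes of a transcript stays open, because no dye swap was made and the same orientation on all arrays could also give the correlation of 0.695 across genes. A response to the siRNA other than through Eif4g3 stays open too, because the series compares Eif4g3 siRNA with control siRNA only. An effect of Eif4g3 knockdown on transcript abundance therefore stays a hypothesis.

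The higher interferon-stimulated list in total RNA was weighed in the same way. An intensity-dependent bias is argued against by 10000 random lists matched on signal, whose middle 95% of medians ran from -0.20 to 0.05 and of which the list's 0.39 was at percentile 100. A single total RNA array as the driver is argued against by an adjusted p of at most 1.47e-04 with each left out in turn. Members that vary together from array to array remain a candidate explanation, since the adjusted p was 0.656 with an estimated correlation. A response to the siRNA itself could not be examined apart from the knockdown, because 1 Eif4g3 siRNA sample was set against 1 control siRNA sample per array.

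Over-representation of long non-coding transcripts was tested among the 316 genes lower in heavy polysome RNA of control siRNA cells. With gene types looked up by symbol or single synonym, which covers 276 of the 316 genes (87.3%), 25 of 197 long non-coding genes were lower (12.7%) and 245 of 12898 protein-coding genes (1.90%). Fisher's exact test across genes, which are not independent replicates, gave a two-sided p of 3.06e-13. Without the genes of the nuclear and non-coding list, whose low values had been seen first, 23 of 192 long non-coding genes were lower (Fisher's exact p = 8.24e-12). In 10000 random draws of protein-coding genes matched on mean signal, the middle 95% had 0 to 4 lower genes and the highest had 8. With 1 array left out in turn, the long non-coding genes lower ranged from 25 of 197 (without total RNA array 1) to 7 of 197 (without heavy polysome array 2, where 70 protein-coding genes were lower), with p of 1.55e-04 or below. An earlier form of the test looked up types by transcript accession. It held only 2 long non-coding genes of 10823, left out Gas5 and Malat1, covered 195 of the 316 genes (61.7%) and gave a p of 1, so it was void and was replaced. That long non-coding transcripts are poorly loaded with ribosomes may account for part of these genes, and most of the lower genes with a type were protein-coding.

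In the 35 splits of the 8 arrays into 4 and 4, only the real split, 1 of 35, gave as many genes in the control channel (318, highest other 33), the smallest share that 35 splits can give. Chance can be excluded for that count only if the 8 arrays are independent, which the labels do not state: they lie on 5 slides, each with 1 fraction, and the log ratios of heavy polysome arrays 2 and 4 correlated at 0.884. The count was 276 with slide as a random block, 0 by limma without the 3 arrays of lowest correlation and 27 in the Cy5 channel. For the difference between fractions, all 35 of 35 splits gave at least the real 0 (highest other 0), which a real count of 0 fixes in advance, so these splits say nothing about chance. For total RNA, turning the signs of single arrays gives 8 patterns, of which 1 gave as many as the real 644 (highest other 0), and for heavy polysome RNA likewise 1 of 8 (real 1310, highest other 0). With 8 patterns a share below 0.05 cannot be reached.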
